A study of Mus musculus with 13 samples.

How the data were processed

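Liver genomic DNA from 13 mice was measured by targeted bisulfite sequencing, in which unmethylated cytosines are converted and read as thymine, so that the share of unconverted reads at a position gives its methylation. By the labels' diet field, 7 mice were fed low fat/low sucrose and 6 were fed high fat/high sucrose. Sample titles carry a prefix, G1 or G2, whose meaning the labels do not give. In the low fat/low sucrose group 4 mice had G1 and 3 had G2, and in the high fat/high sucrose group each prefix had 3 mice. Per the labels' protocols, libraries were made with an Agilent methylation capture kit, with 9 cycles of amplification after conversion and 6 cycles of indexing amplification. The capture design named in the labels is a mouse exon design of 52 Mbp. By the authors' flags only 13.3% of the listed sites lay in exons, and which probes were used could not be checked. The submitters' processing notes name CASAVA 1.8, Trim Galore, Bismark and methylKit and the genome build mm9, without their settings.

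The values come from 1 table, the authors' own comparison of the 2 diets. Per the file headers, each row of the authors' table gives a p-value, a q-value, a methylation difference in percentage points and the average percent methylation of each diet. It also gives a distance to a feature, flags for CpG islands, island shores, promoters, exons and introns, a RefSeq transcript and a gene symbol. The feature was read here as a transcription start, as sites with the promoter flag lay at most 1001 bp from it. The sign of the difference column matched high fat/high sucrose minus low fat/low sucrose at all 23904 sites. The difference column is not the difference of the averages: the median gap between them was 0.90 points and the largest was 13.9 points. The weighting of either column, the test and the method behind the q-values are not given in the sources used here. The largest q in the table was 0.0100 and the smallest absolute difference was 5.00 points, so the table holds sites already filtered by both. Values per mouse, read counts and sites that did not pass were not analysed here. The depth behind each site is therefore unknown, no SD or n is given, and the spread between mice does not enter any test run here.

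Positions are those of the table, in mm9. The names chr20, chr21 and chr22 were read as X, Y and the mitochondrial chromosome. Of 214 chr20 sites whose gene was placed by the RefSeq gene table for GRCm38.p6, 213 lay on X. That table was used for names and chromosomes only. Of the 9100 symbols in the table, 8494 were current there and 570 more were synonyms. At 41 sites the symbol had become a calendar date, as spreadsheets do to the septin genes, and 39 were given a gene by their transcript. In all, 21268 sites were given 1 of 9125 genes and 2636 had none. A gene here was read as the one whose transcription start is nearest, so a named site need not lie in the gene. The median distance was 8900 bp and 47.6% of sites lay over 10000 bp away. Reads from near-identical copies, such as clustered protocadherins and olfactory receptors, may be placed on the wrong copy, so such sites are uncertain.

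All tests compare sites or genes within the list and do not stand for tests across mice, since every site was measured in the same 13 animals. Sites within 1000 bp of each other were joined to clusters, and each cluster took the direction of its site of smallest p. The share of clusters higher in high fat/high sucrose was compared with an even split by an exact two-sided binomial test, with exact Clopper-Pearson 95% intervals. Those intervals cover counting of sites only. Direction was compared between the clusters in a genomic feature and all others by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 7 features. No background of tested sites was used, so no enrichment of features or gene lists was computed.

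Before the data were examined, 24 gene lists were fixed, 8 of them markers of liver cell types and adipocytes. For each list the share of its sites that were higher was set against 10000 random gene lists of the same size matched on sites per gene, a two-sided permutation test over genes, with Benjamini-Hochberg adjustment over the 24 lists. The smallest p this can give is 0.00019998. The share was used for calls because differences have no values near 0, which makes a median jump between rises and falls. The named genes follow a rule also fixed in advance: the 10 genes with the largest rise, the 10 with the largest fall, the 10 with the most sites, and up to 3 genes per list with the smallest p. Some genes that the rule takes are not reported here. Other genes are named as chosen after their values were seen, or within a count over their list. The list test was tested on 20 simulated data sets with the 9125 genes. Of 400 simulated unchanged lists, 4.50% had a p under 0.05. Their directions were drawn without regard to methylation level, so this rate does not cover real lists whose levels differ from those of random lists. Of 380 simulated lists of 8 or more genes with 90% of sites higher, 89.5% were recovered at that limit, against 10% of 20 lists of 5 to 7 genes. In these lists each site was drawn on its own and p was not adjusted. Recovery of real lists, whose neighbouring sites move together, at the adjusted limit may be lower.

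Alternatives were stricter limits on size and q, clusters within 100 bp, sites or genes counted singly, promoter sites alone, equal weight for each gene, sites within 10000 bp of a start, comparison with sites of the same mean level in 20 bins, and leaving out X, Y and mitochondrial sites. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.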

Results

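DNA methylation was measured in the livers of 13 mice by targeted bisulfite sequencing, 6 fed a diet high in fat and sucrose and 7 fed one low in both. The comparison asks where liver methylation differs between the 2 diets. The authors' deposited table holds 23904 sites that passed the authors' limits, each with an average methylation level per diet. Read depth per site and values per mouse were not analysed here, so depth is unknown and no spread between mice can be given.

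Liver methylation differed in both directions, and rises in high fat/high sucrose mice were the more frequent. In the authors' deposited table, 13772 sites were higher and 10132 were lower in high fat/high sucrose. The median rise was 11.7 percentage points and the median fall was -11.6 points in the authors' deposited table. Joined within 1000 bp, the sites formed 18409 clusters, of which 10228 were higher and 8181 lower. The share higher was 55.6% (exact 95% interval 54.8 to 56.3), which differed from an even split (exact binomial test over clusters, p = 1.74e-51). This p treats clusters as units and carries no variation between mice.

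**Figure D1:**
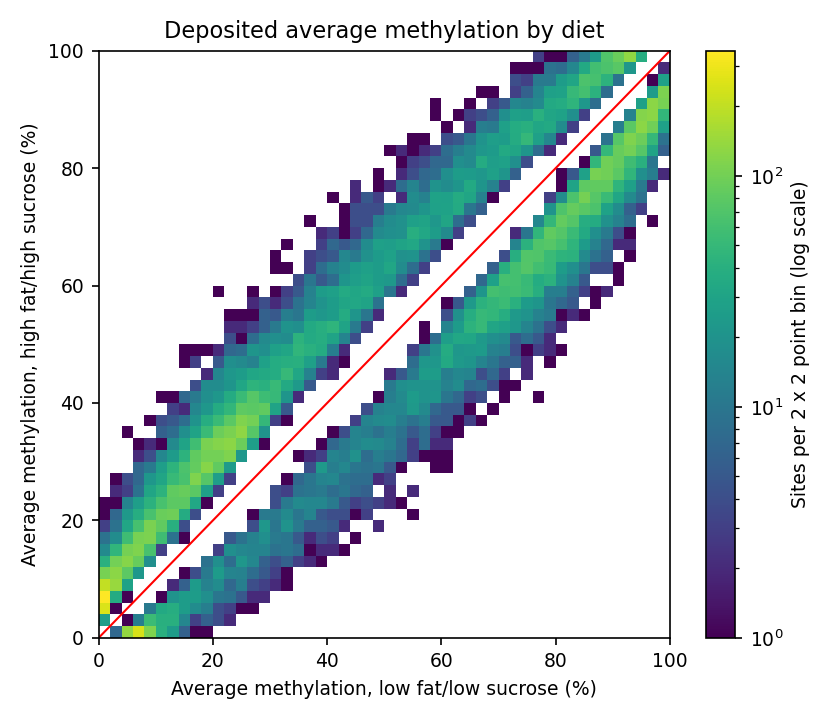
Average methylation (%) at the 23904 sites in low fat/low sucrose (x axis) and high fat/high sucrose (y axis), as counts of sites per bin on a log colour scale; the red line marks equal averages. Few sites lie along the line, as the averages differed by under 5 points at 499 sites, and 13772 sites have a positive difference.

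The largest single rise was at Mst1r, which encodes the receptor tyrosine kinase RON. In the authors' deposited table the Mst1r site on chromosome 9 at 107809572, in a promoter and exon, averaged 21.8% in low fat/low sucrose and 59.0% in high fat/high sucrose, a listed difference of 39.7 points. Next in the authors' deposited table came Arhgap27 (33.7 points), Mark4 (33.5), Slc47a2 (33.4) and Erp27 (32.3). Rhobtb1 (32.0), Padi3 (31.9), Slc27a1 (31.7), Nmnat2 (31.7) and Blvra (31.6) completed the 10 largest rises in the authors' deposited table. Slc27a1 encodes a fatty acid transport protein and Blvra a biliverdin reductase. The Rhobtb1 site lay 61553 bp and the Nmnat2 site 77173 bp from the start, per the authors' deposited table.

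The largest fall was at Ulk1, a kinase that starts autophagy. In the authors' deposited table the Ulk1 site, in an exon on chromosome 5 at 111220094, averaged 55.0% in low fat/low sucrose and 20.2% in high fat/high sucrose, a listed difference of -32.4 points. It was followed in the authors' deposited table by B3galt4 (-31.2), N4bp1 (-31.2), the tyrosine kinase gene Src (-30.8), Lsm6 (-30.2) and the Notch target Hes1 (-30.0). Cacfd1 (-29.9), Dctpp1 (-29.8), Pcdh1 (-29.6) and Mras (-29.4) were the others in the authors' deposited table. The Lsm6 site lay 79170 bp and the Hes1 site 57384 bp from the nearest start, per the authors' deposited table.

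Each of the 10 genes with the most sites had sites moving both ways. Among them the transcription factor gene Runx1 had 25 sites (8 higher, 17 lower), Foxp1 had 21 (6 higher, 15 lower) and Etv6 had 17 (11 higher, 6 lower). Onecut1, a hepatocyte transcription factor gene, had 21 sites, 15 of them higher, and the fatty acid elongase gene Elovl6 had 17, 15 of them higher. Neurl3 had 17 (13 higher), Septin9 17 (7 higher), Atxn7l1 17 (7 higher), Tiam1 18 (5 higher) and Mbp 18 (8 higher). Among the 2729 genes with at least 3 sites, 920 had all their sites in one direction, 629 higher and 291 lower. When directions were shuffled among sites of the same mean level, the median count was 512.5 and the highest of 200 shuffles was 558. These shuffles moved sites singly, although 97.1% of neighbouring pairs within 100 bp shared a direction. Nearby sites of a gene could therefore raise the count above the shuffles. Whole clusters were not shuffled, so agreement across a gene beyond its neighbouring sites was not tested.

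The share of clusters that were higher in high fat/high sucrose was larger within CpG islands, shores and promoters than in the rest. Of the clusters in CpG islands, 64.6% were higher, against 54.9% of the rest (Fisher's exact test, adjusted p = 1.06e-10). In island shores 63.6% were higher, against 53.6% (exact test, adjusted p = 1.05e-27), and in promoters 63.8%, against 53.9% (adjusted p = 1.95e-24). Exons also had more rises than the rest, 58.6% against 55.1% (exact test, adjusted p = 0.00192). Introns had fewer, 53.9% against 57.2% (exact test, adjusted p = 8.45e-06), as did clusters outside islands and shores, 52.6% against 63.9% (adjusted p = 1.64e-41). Clusters with no gene feature showed no difference that passed the test, 55.4% against 55.6% (exact test, adjusted p = 0.816). By location, 6.50% of clusters were in islands, 19.9% in shores, 17.2% in promoters, 12.4% in exons and 49.0% in introns, while 35.2% had no gene feature and 73.6% were outside islands and shores.

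Direction also followed the level of methylation. Of sites whose 2 averages had a mean of 20 to 30%, 87.3% were higher in high fat/high sucrose, and of those at 70 to 80%, 30.0% were. Clusters with the levels of those in promoters would be higher in 63.2% of cases, against the 63.8% observed. For islands the share given by level was 62.7% and for shores 61.5%. It was 53.3% outside both, against 52.6% observed, 56.2% for exons, against 58.6%, 55.2% for introns, against 53.9%, and 54.6% with no gene feature, against 55.4%.

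**Figure D2:**
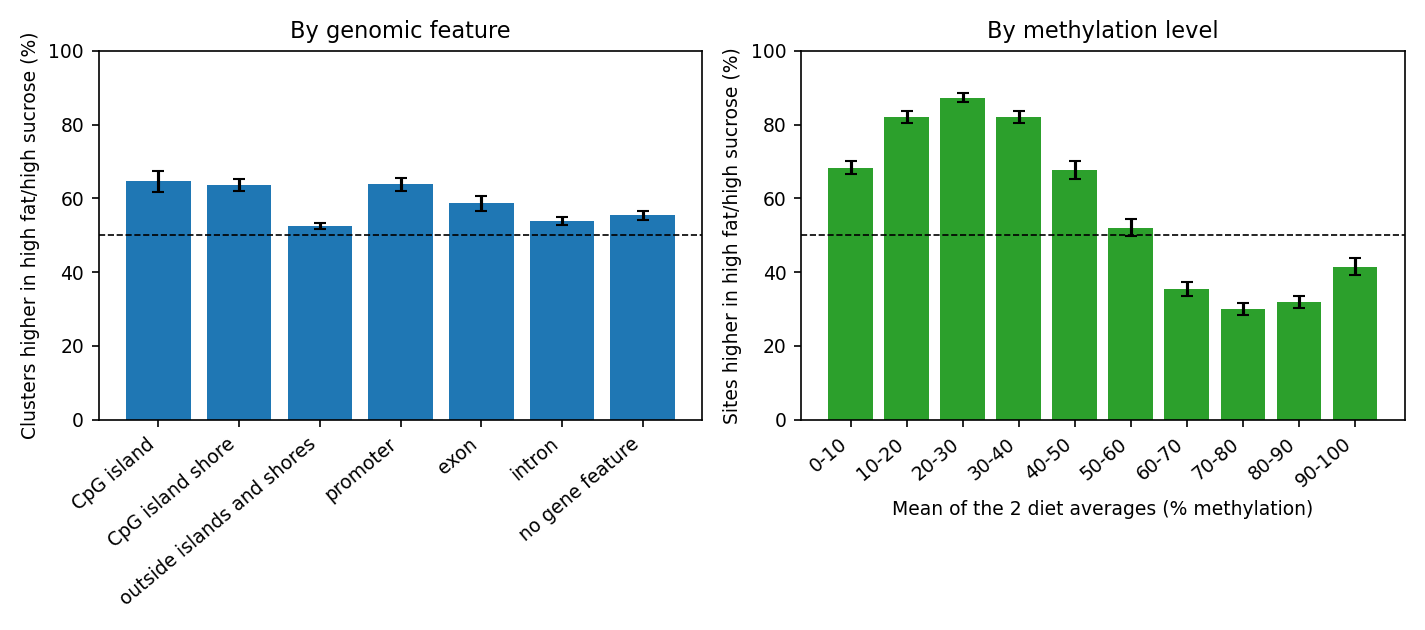
Left, clusters of sites that were higher in high fat/high sucrose (%) by genomic feature; right, sites higher (%) by the mean of the 2 diet averages (% methylation). Bars are shares, error bars are exact 95% binomial intervals over clusters or sites, and dashed lines mark an even split; shares peak at 87.3% for levels of 20 to 30%.

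Genes of fatty acid and triglyceride synthesis carried mostly rises. Of 84 sites at 22 genes of this list, 74 (88.1%) were higher in high fat/high sucrose, against a median of 58.9% and a central 95% range of 43.1 to 73.7% in random gene lists (permutation test over genes, p = 0.00019998, the smallest possible, adjusted p = 0.00480). Sites were all higher at 15 genes, all lower at 0 and mixed at 7. All sites were higher at Acly (5 of 5), which makes cytosolic acetyl-CoA, at the desaturase genes Scd1 (6 of 6) and Fads1 (5 of 5), and at the glycerolipid synthesis genes Gpam (8 of 8) and Dgat2 (7 of 7). Acaca (2 of 2), Acacb (3 of 3) and Fasn (1 of 1) went the same way. Scd2 (2 of 4), Srebf1 (1 of 2), Mlxipl (1 of 2) and Fads2 (1 of 3) had both directions.

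At single sites of this list, an intronic site of Scd1 on chromosome 19 at 44479107 averaged 41.5% in low fat/low sucrose and 60.1% in high fat/high sucrose in the authors' deposited table, a listed difference of 19.6 points with p listed as 0. The Fads1 intronic site on chromosome 19 at 10258756 averaged 12.6% and 29.4% in the authors' deposited table (difference 20.3 points, q = 8.85e-08). For Elovl6, the intronic site on chromosome 3 at 129251912 averaged 83.7% and 97.2% in the authors' deposited table (difference 14.1 points, q = 2.09e-07). Over the list's 84 sites the mean of the averages was 37.7% in low fat/low sucrose and 47.9% in high fat/high sucrose in the authors' deposited table. Hepatocyte marker genes had a similar share of rises, 24 of 27 sites (88.9%). With promoter sites alone, 8 of 10 lipogenesis sites were higher and the call was lost (adjusted permutation p = 1).

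**Figure D3:**
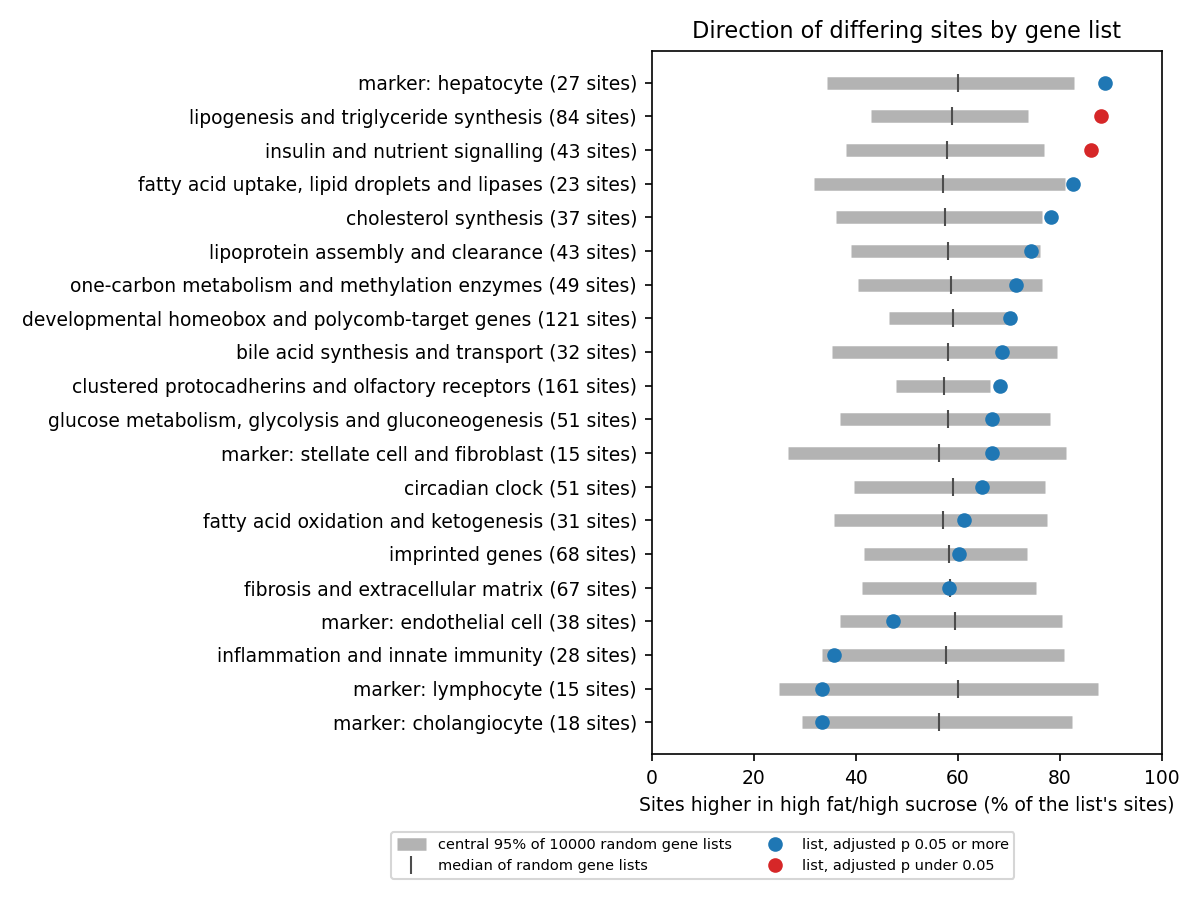
Sites higher in high fat/high sucrose (% of each list's sites; points) for the lists with at least 5 genes, with the central 95% range (grey bars) and median (ticks) of 10000 random gene lists matched on sites per gene. Lipogenesis (88.1%) and insulin signalling (86.0%), in red, have an adjusted p under 0.05.

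**Figure D4:**
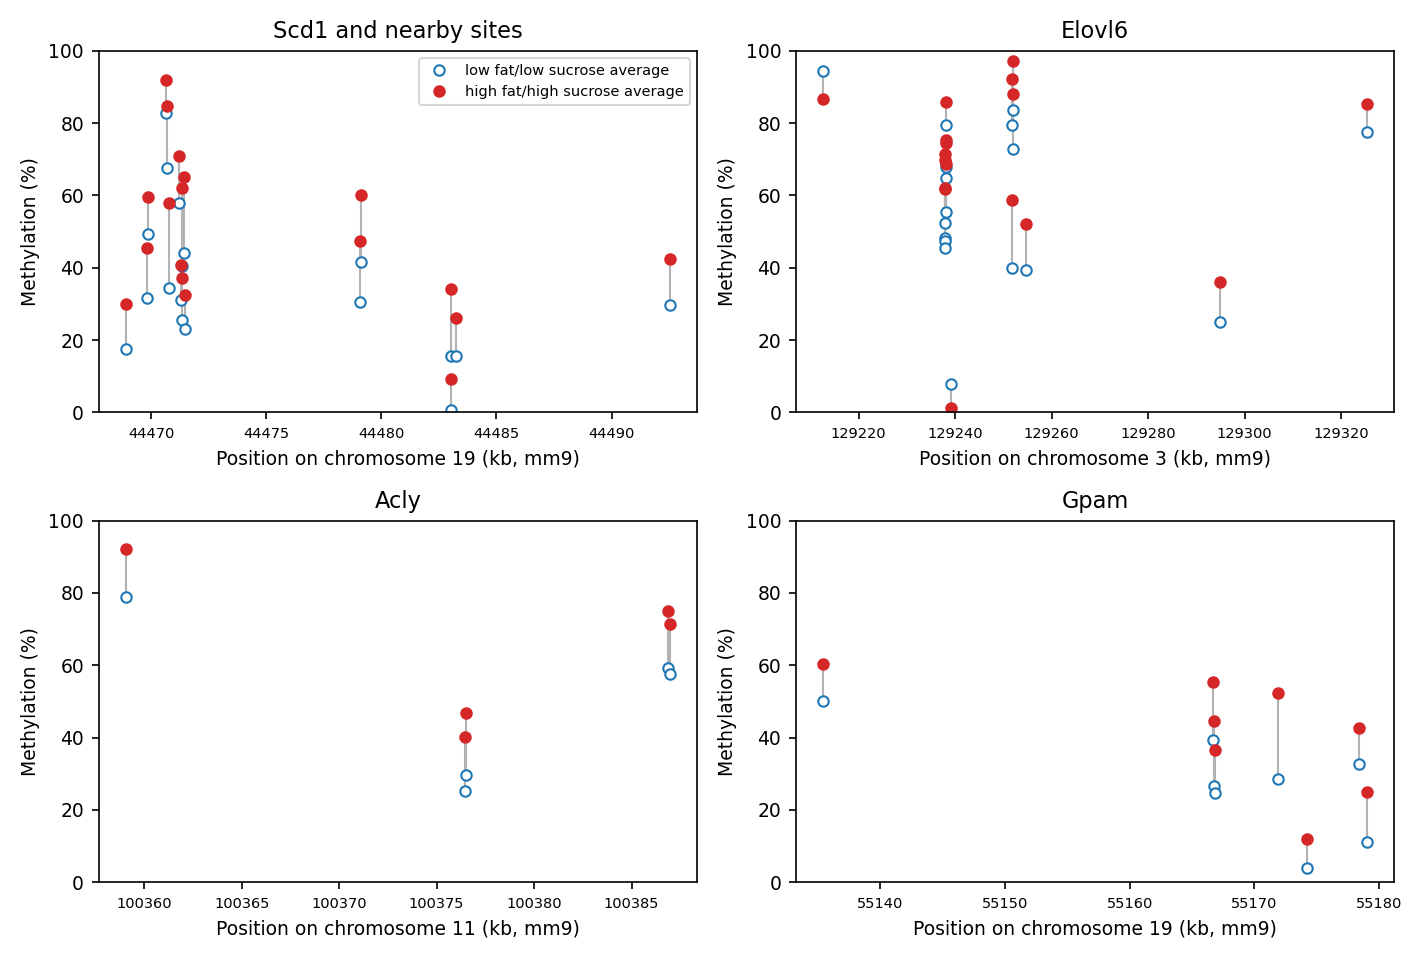
Average methylation (%) by diet at each listed site of Scd1 with a nearby group of sites, Elovl6, Acly and Gpam, against position (kb, mm9); lines join the averages of a site (open circles low fat/low sucrose, filled circles high fat/high sucrose). The genes were chosen after their values were seen, and Elovl6 has 15 of 17 sites higher.

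Insulin and nutrient signalling genes also carried more rises than random lists. Of 43 sites at 16 genes, 37 (86.0%) were higher (adjusted permutation p = 0.0144), among them all sites of the insulin receptor adaptor genes Grb10 (7 of 7), Irs2 (4 of 4) and Irs1 (3 of 3). A single cluster held 6 of the 7 Grb10 sites, so those are not independent. In the authors' deposited table the Grb10 promoter site on chromosome 11 at 11938209 rose by 14.7 points and a Rictor site by 14.8 points. The 1 site at Insr, the insulin receptor gene, was lower. The share stayed high but the call was lost with equal weight per gene (84.2%, adjusted permutation p = 0.0624), within 10000 bp of a start (19 of 21 sites, adjusted permutation p = 0.110) and in promoters (4 of 4 sites, all of 1 gene, adjusted permutation p = 1). Against sites of the same mean level the excess was 12.9 points (adjusted permutation p = 0.536).

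The other metabolic lists did not pass the test. For fatty acid uptake, lipid droplets and lipases, 19 of 23 sites were higher (adjusted permutation p = 0.113), including 4 of 4 at Lpl, which encodes lipoprotein lipase. Cholesterol synthesis had 29 of 37 higher (adjusted permutation p = 0.140), with 7 of 7 at Fdft1, the squalene synthase gene. Lipoprotein genes had 32 of 43 (adjusted permutation p = 0.230) and bile acid genes 22 of 32 (adjusted permutation p = 0.642), with 8 of 8 at Klb, the FGF co-receptor gene. The 8 Klb sites lay in a single cluster, so they are not independent. Fatty acid oxidation and ketogenesis had 19 of 31 (adjusted permutation p = 0.860), with 4 of 4 higher at Ppara and 5 of 7 lower at the ketone body gene Bdh1. Glucose metabolism had 34 of 51 (adjusted permutation p = 0.718), one-carbon metabolism and methylation enzymes 35 of 49 (adjusted permutation p = 0.346), and xenobiotic enzymes 3 of 4 (adjusted permutation p = 0.875).

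The values that follow are for the site of smallest p of each gene, which need not follow the gene's other sites. A site in the promoter of Gnmt, which encodes a glycine methyltransferase, averaged 3.33% in low fat/low sucrose and rose by 18.5 points in the authors' deposited table, with 2 of 3 sites of the gene higher. Listed differences were -24.7 points at Acads, a short-chain acyl-CoA dehydrogenase gene, and -19.3 points at the gluconeogenic gene Pck1 in the authors' deposited table. Acads had this 1 site, whereas 3 of 5 sites of Pck1 were higher. Rises in the authors' deposited table were 16.2 points at Apoe, 18.4 at Acadm, 15.9 at Klb, 16.0 at Pnpla2 and 21.7 at Onecut1. Of the sites of these genes, 1 of 3 was higher at Apoe, 1 of 2 at Acadm, 8 of 8 at Klb, 2 of 2 at Pnpla2 and 15 of 21 at Onecut1.

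Lists outside metabolism did not pass the test either. Inflammation genes had 10 of 28 sites higher (35.7%, adjusted permutation p = 0.230), with 1 of 8 higher at the cytokine signalling kinase gene Jak2. At Irf1, 2 of 4 sites were higher, and the site of smallest p had a difference of -24.6 points in the authors' deposited table. Fibrosis and matrix genes had 39 of 67 higher (adjusted permutation p = 0.979), with 10 of 15 at Smad3 and 2 of 9 at Smad7. Circadian genes had 33 of 51 (adjusted permutation p = 0.773), with 6 of 8 at Per2 and 0 of 4 at Csnk1e. Imprinted genes had 41 of 68 (adjusted permutation p = 0.875), with 3 of 10 at Peg13. Developmental homeobox and polycomb-target genes had 85 of 121 (adjusted permutation p = 0.230), with 6 of 6 at Hoxb3 and 3 of 11 at Gata4. Clustered protocadherins and olfactory receptors, for which the placement of reads among similar copies is uncertain, had 110 of 161 (adjusted permutation p = 0.107).

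The share of rises varied among the cell type marker lists, and no marker list passed the test over all its sites. Hepatocyte markers had 24 of 27 sites higher (adjusted permutation p = 0.0624), with 5 of 5 at Arg1 and 3 of 3 at Ttr, and within 10000 bp of a start they had 15 of 15 (adjusted permutation p = 0.0480). The 5 Arg1 sites lay in a single cluster, listed at -21182 to -20870 bp from the start, so they are not independent. Markers of endothelial cells had 18 of 38 higher (adjusted permutation p = 0.566), with 4 of 11 at Erg and 1 of 5 at Cdh5. Lymphocyte markers had 5 of 15 (adjusted permutation p = 0.337), with 0 of 6 at Ptprc but 3 of 3 at Zap70. Cholangiocyte markers had 6 of 18 (adjusted permutation p = 0.256), with 0 of 4 at Spp1 but 2 of 2 at Cftr. Stellate cell and fibroblast markers had 10 of 15 (adjusted permutation p = 0.773), neutrophil markers 4 of 5 (adjusted permutation p = 0.773), macrophage markers 1 of 3 (adjusted permutation p = 0.90) and adipocyte markers 2 of 5 (adjusted permutation p = 0.860). In the authors' deposited table, differences were -22.3 points at the Spp1 promoter, -18.1 at Cdh5, -16.0 at the Lck promoter and 22.4 points at Vwf. Of the sites of Lck 1 of 3 was higher, and of those of Vwf 4 of 4.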

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

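Direction over clusters lay between 55.6% and 60.4% higher under every alternative run and kept its side of the test. The limits on q under 0.001, mean level of 20 to 80%, distance to a start and difference of averages, and the comparison by level, were chosen after the data were seen, as was leaving out X, Y and mitochondrial sites for direction. Sites numbered 15528 at 10 points or more, 240 at 25 points or more, 5626 at q under 0.001 and 14268 where the averages differed by 10 points or more, against 23904, as stricter limits keep fewer sites. Lists passing the test numbered 2 in the main comparison, 0 with promoter sites alone, 1 with equal weight per gene and 1 against sites of the same mean level; the cause was not tested, though promoters hold fewer sites. Within 10000 bp of a start 2 lists passed, lipogenesis and hepatocyte markers. Of 93 list results under alternatives, 87 kept their side of the threshold. In 16 the share moved to the other side of its reference, in none of them for a list that passed the main test. The reference was the share expected from mean level in 5 of these and the random median in the rest.

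With each site counted alone, islands held 7.12% of sites, shores 20.5%, exons 13.3%, areas outside islands and shores 72.4% and areas with no gene feature 34.4%. These differ from the shares of clusters because a cluster counts once, by its site of smallest p, however many sites it holds. At 10 points or more the shares of clusters were 3.94% in islands, 18.5% in shores, 77.5% outside both, 13.7% in promoters and 36.8% with no gene feature; the cause was not tested. Genes numbered 4755 with 2 or more sites and 1021 with 5 or more, against 2729 with 3 or more. All 100 named sites kept their sign by the difference of averages and moved by under 1.5 times.

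Planned tests that need values per mouse, reads or sites that did not pass were not run: other models per site, coverage minimums, unadjusted p under 0.05, the title prefix as covariate, logit offsets, leaving out mice, mean levels over all sites and enrichment of lists. No paired analysis was possible because values per mouse were not analysed here. Coverage limits every average by an unknown amount.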

Other observations

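Groups of sites, looked for after the values were seen, marked regions that moved as a block. Of 171 groups with at least 5 sites, each within 1000 bp of the next, 115 were all higher in high fat/high sucrose, 31 all lower and 25 mixed. On chromosome 10 at 116855280 to 116856080, a stretch with no gene in the table, 14 of 14 sites were higher, with mean averages of 35.3% in low fat/low sucrose and 55.9% in high fat/high sucrose in the authors' deposited table. In a group named for Gad2, a glutamate decarboxylase gene, 13 of 13 sites on chromosome 2 at 22442932 to 22445521 were lower, from 47.3% to 31.1% in the authors' deposited table. Their listed distances from the Gad2 start were -34915 to -32326 bp, and all 13 carry an intron flag, so they need not lie in Gad2. Near Scd1, on chromosome 19 at 44468900 to 44471466, 12 of 12 sites were higher, from 42.1% to 56.5% in the authors' deposited table; they lie 10734 to 13300 bp from the Scd1 start, have no gene symbol, and 11 carry the exon flag and 11 the promoter flag of another transcript start. Single groups at Neurl3 (11 of 11) and Art3 (9 of 9) were also all higher. Groups named for Ncoa3, a nuclear receptor coactivator gene, and Txnip, a thioredoxin-interacting protein gene, had 9 of 9 and 8 of 8 sites lower. The Ncoa3 group was listed at -37748 to -37490 bp from the start, without a promoter, exon or intron flag. Over all its sites Neurl3 had 13 of 17 higher, Gad2 14 of 15 lower, Ncoa3 12 of 13 lower and Txnip 8 of 9 lower.

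Of the 126 genes with at least 10 sites, 8 had all sites higher and 0 had all lower. They were the transcription factor genes Gata2 (15 sites) and Bcl11b (13), Phlda1 (11), Pdzrn3 (11), Rhof (11), Aars (10), Gzf1 (10) and Rn4.5s (10), a small RNA gene with many copies whose reads are hard to place. The sites of these 8 genes spanned 2193 bp (Aars) to 275849 bp (Pdzrn3). A single group held 9 of 10 sites at Aars, 9 of 10 at Gzf1 and 10 of 11 at Rhof, so those counts are not independent. Acss2, which makes acetyl-CoA from acetate and was chosen after its value was seen, had a site with p listed as 0 and a rise of 24.5 points in the authors' deposited table, and so did Enpp3 with 19.7 points. On X, 47.6% of 208 clusters were higher, against 55.6% on autosomes (Fisher's exact test, p = 0.0207, not adjusted and chosen after the values were seen).

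In the patterns that follow, the tests of neighbours over 1000 bp apart, of the mean level of lipogenesis sites and of lipogenesis against other pooled lists were chosen after their results were seen.

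High fat/high sucrose averages lay nearer to 50% than low fat/low sucrose averages at 16944 of 23904 sites (70.9%). Noise from few reads should matter least at the smallest p, yet there the share was 73.9% with 1 site per cluster (95% interval 72.0 to 75.8). Sites near 0 and 100% do not alone give the pattern, since with both averages between 10 and 90% the share was 70.5%. The authors' limits on q and size act at every level, so that cut cannot exclude a part for them. A shift in cell composition stays open. At their site of smallest p, 9 of 10 hepatocyte marker genes rose, against 21 of 40 markers of the other liver cell types. Adipocyte markers were left out of this comparison, as set before it was run. The difference was 37.5 points (95% interval 3.78 to 54.6, Fisher's exact test, p = 0.0366). The hepatocyte markers' excess of rises over sites of the same mean level was 5.23 points, at percentile 66.9 of random lists. This cannot tell composition from level, since the expectation by level comes from these same sites and holds the pattern itself. Of the 10 genes, 2 (Apoa1 and Apob) also stand in the lipoprotein list. A change of methylation within cells by diet, and the spread between mice, were not tested.

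Neighbouring sites moved together. Within 100 bp, 97.1% of 3313 neighbouring pairs had the same direction. That share lay above the highest of 1000 shuffles among sites of the same mean level (64.8%), so a shared mean level alone does not give it. Reads that cover both neighbours may give it at such distances, which stays open, but pairs over 1000 and up to 10000 bp apart still had 56.1%, against a highest of 200 shuffles of 55.6%. The share was 75.2% over 100 and up to 1000 bp and 52.1% over 10000 and up to 100000 bp, the latter within the shuffles. Regional regulation and chance differences between the 13 mice, which neighbours share, are both open and were not tested.

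The excess of rises at lipogenesis genes was weighed against level, single genes and a rise of hepatocyte genes as a whole. Against sites of the same mean level the excess was 22.5 points (permutation test over genes, adjusted p = 0.0144). Leaving out each gene in turn was done on the plain share of rises, without the comparison by level. The largest p was 0.0009995 (permutation test over genes), the smallest that 2000 random lists allow. Level and single genes were not removed together. Neither mean level nor 1 gene alone therefore accounts for the excess. The mean level includes the high fat/high sucrose average, and the low fat/low sucrose level by itself was not tested. The share was 17.6 points above that of 5 other hepatocyte lists pooled (124 of 176 sites, permutation test over genes, p = 0.0230), but 13.7 points above all 10 metabolic and hepatocyte marker lists pooled (247 of 332, p = 0.0556) and 13.2 above 8 of them (p = 0.0632), so a rise of hepatocyte genes as a whole is not excluded. Cell composition could also contribute, since hepatocyte markers had 88.9% of sites higher. Their excess over sites of the same mean level was 5.23 points (permutation test over genes, adjusted p = 0.843). That value does not weigh against composition, as the expectation by level holds the same pattern. Variation between mice stays open too. A response of these loci to the diet is a hypothesis that values per mouse would have to test.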
